A study of Rattus norvegicus with 6 samples.

How the data were processed

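Total RNA from the pineal glands of 6 rats was sequenced, 1 library per rat, and 3 kinds of deposited file were used. For each library the authors deposited a table in the column format of the circRNA caller CIRI, which per the file headers gives counts of back-splice junction reads, counts of reads across the same ends that are not back-spliced (called linear reads here), and the fraction of reads at the ends that is circular. The deposited fraction equals 2 times the back-splice reads divided by that number plus the linear reads. These are the main tables. For each library the authors also deposited a candidate list in the column format of the caller find_circ, with counts of reads across each junction (the second caller). For the whole series they deposited circRNA values in TPM. Versions of both callers, the aligner and their settings are not given in the sources used here. The submitters' processing notes name DESeq and the mouse build mm9, whereas the files have rat Ensembl gene IDs and autosomes numbered up to 20; the build is therefore uncertain, and coordinates are printed as the files give them, counted from 1; starts in the second caller's lists count from 0 and were raised by 1.

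Several properties were checked in the values. The main tables list only circRNAs with at least 2 back-splice reads, and no listing has a circular share below 9.09%, that is, more than 20 linear reads per back-splice read. A circRNA can therefore drop out of a table because its linear RNA is high, and an absent entry was counted as 0 but is described as not listed. The second caller's lists start at 2 reads and have no linear reads. The authors' TPM table holds the 1413 circRNAs that both callers found in the same library at least once. Its values equalled the mean of both callers' reads, rounded down, divided by a length and scaled to a common total per library, at every intergenic circRNA with a value above 0 (tolerance 0.1%); values were above 0 only where both callers listed the circRNA in that library. The length was the full genomic span for intronic and intergenic circRNAs but a shorter length for most exonic ones (medians over circRNAs of 8560, 12247 and 522 bases). TPM therefore weighs exonic circRNAs more: they held 63.5% of the averaged reads and 93.3% of the TPM, as means over libraries. TPM keeps no depth and was used only as an alternative.

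Back-splice counts of the main tables were joined by chromosome, start and end. Samples were grouped by rat number as the labels give it; the labels conflict on day and night, and no value was used to decide. All 6 libraries carry 1 flow cell lane in their read names, and no batch was given. Each pair of libraries differed beyond sampling noise over the circRNAs listed in all 6 (chi-square divided by its degrees of freedom at least 1.39, p at most 1.9e-05), so no library was taken as a duplicate. The labels describe separate animals.

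circRNAs with at least 2 reads in at least 3 libraries (772) were tested with edgeR 4.0.16 (quasi-likelihood, TMM normalization) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 difference is its size divided by the square root of the F statistic. Host genes were tested in the same way on summed reads of circRNAs with 1 host gene. The circular share was tested with limma 3.58.1 (trend) on log2 of back-splice over linear reads, each plus 0.5, over circRNAs listed in all 6 libraries. Numbers per library were compared with exact two-sided permutation tests, which with 3 against 3 have 10 splits and a smallest p of 0.1. These tests and their alternatives were chosen before the data were examined: other normalization (RLE, library size only), other filters, DESeq2 1.42.0, limma-voom, the second caller's counts, circRNAs found by both callers, the TPM values with limma (pseudocount 0.760, which is 0.5 of the smallest value above 0, or 1), and leaving out each rat. Tests restricted to circRNAs listed in all 6 libraries, tests of linear reads, the authors' averaged reads and the second caller's sharing counts were added after the data were seen.

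By the rule for named circRNAs, per direction up to 10 with the largest log2 difference were named among those past the threshold whose groups did not overlap, filled to 5 by unadjusted p, together with the 10 of highest mean count and, for the circular share, the 3 of smallest p per direction. For linear reads 5 per direction were named, 1 per locus, by a rule set after the data were seen. Where several circRNAs shared a host gene or an end, the locus was represented by the circRNA with most back-splice reads. Host genes appear in the files as Ensembl IDs only; none of 1056 IDs could be matched to a symbol in the RefSeq table at hand, so few IDs are printed and gene lists fixed beforehand (night-raised pineal transcripts, clock, melatonin synthesis, phototransduction, adrenergic signalling, synaptic ribbon, circRNA hosts of brain, splicing factors, chromatin modifiers and cell type markers) were not tested.

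On data simulated from the libraries' means, sizes and dispersions, the circRNA test recovered 13 of 100 circRNAs changed 2-fold and 14 of 100 changed 4-fold, with 1 false among 28 calls (common biological coefficient of variation 80.7%). Over circRNAs listed in all 6 libraries (11.9%) it recovered 34 of 46 and 45 of 45, with 4 false among 83 calls. The host gene test recovered 3 of 79 and 17 of 78. The linear read test recovered 41 of 46 and 45 of 45, and the circular share test 30 of 46 and 39 of 45. The simulations did not apply the main tables' minimum circular share, so no simulated change took a circRNA out of the 273. The 80.7% comes from a fit that counts unlisted entries as 0, so it is not variation between rats alone. Figures were drawn with matplotlib 3.10.9.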

Results

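Circular RNAs (circRNAs), closed RNA loops recognised by reads across a back-splice junction, were measured in the pineal gland, the melatonin-secreting gland of the brain, of 6 rats aged 8 weeks, with 1 library of total RNA per rat. The study compared glands taken by day and by night. The labels contradict each other on which rats were which: the titles and time tags place rats C01 to C03 at night (4:00) and rats C04 to C06 in the day (16:00), whereas the treatment protocol describes C01 to C03 as the light group (16:00 to 17:00) and C04 to C06 as the dark group (04:00 to 05:00, under red light). The groups are therefore named by rat number here (n = 3 each), each difference is given as C01 to C03 relative to C04 to C06, and no difference is assigned to day or night. Back-splice reads per library in the main tables, from C01 to C06, numbered 21038, 15506, 17368, 20680, 22265 and 19501.

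The pineal libraries held 2228 distinct circRNAs in the main tables. Of these, 1336 (60.0%) were annotated as exonic, 230 (10.3%) as intronic and 662 (29.7%) as intergenic. A single host gene was given for 1563, spread over 1052 host genes, of which 742 had 1 circRNA and 22 had 5 or more. Only 273 circRNAs (12.3%) were listed in all 6 libraries, and these carried 71.2% of the back-splice reads. A further 1094 were listed in a single library, with a median of 4 reads.

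Reads were spread unevenly over the circRNAs. The 10 circRNAs with most reads in a library took 21.2% ± 2.02 (SD, n = 6) of its back-splice reads. By mean normalised count, the most abundant was an intergenic circRNA at chr3:104816866-104818862, followed by intergenic chr20:5347661-5414567, intergenic chr2:240854068-240867796, intronic chr6:76591791-76599536 and intergenic chr3:81127393-81143240. The next 4 were exonic circRNAs of a single host gene on chromosome 5, which all began at 167486001 and ended at 167526275, 167581074, 167558250 and 167615430. The tenth was exonic, at chr9:94463647-94481167. The second caller had no reads in any library for 3 of these 10, chr20:5347661-5414567, chr3:81127393-81143240 and chr5:167486001-167615430. The chromosome 5 host gene had the most circRNAs of any, 11 between 167455211 and 167615430, which together held 9.48% of all back-splice reads. These 11 totalled 99328 ± 1795 CPM (reads scaled to a common total, here without TMM) in C01 to C03 and 90462 ± 5178 in C04 to C06 (SD, n = 3 each). The host gene did not pass its own test (log2 difference 0.09, SE 0.07, edgeR adjusted p 0.99). None of the 4 abundant members passed the test applied to all circRNAs, and the log2 differences lay between 0.00 and 0.23. Another circRNA of this host gene, chr5:167516581-167615430, did pass and is among those below that the main tables listed only in C04 to C06.

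The central comparison asked which circRNAs differed between the groups of pineal glands. The clearest differences among circRNAs listed in every library were at chr3:104816866-104818862 and chr4:184195264-184224636, both intergenic and both higher in rats C01 to C03. The first rose from 28257 ± 829 to 44334 ± 6122 normalised CPM, a log2 difference of 0.65 (SE 0.10). The second rose from 9027 ± 397 to 13975 ± 1426, a log2 difference of 0.63 (SE 0.10; SD, n = 3 each). Another 2 circRNAs were lower in C01 to C03. The intronic chr3:172518176-172524861 had 7284 ± 651 against 10488 ± 277 (log2 difference -0.52, SE 0.09), and the intergenic chr2:240854068-240867796 had 25051 ± 1009 against 31274 ± 671 (log2 difference -0.32, SE 0.05). The adjusted p for these 4, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 772 circRNAs, was 0.036, 0.036, 0.049 and 0.049.

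In total 12 circRNAs passed an adjusted p of 0.05, 3 higher and 9 lower in C01 to C03. The other 8 were listed in all 3 libraries of one group and in none of the other. Exonic chr17:77176705-77178100 was listed with 28, 26 and 19 reads in C01 to C03 only. The remaining 7 were listed only in C04 to C06: exonic chr1:244630341-244664389 with 182, 182 and 169 reads, exonic chr13:106859710-106862333 with 97, 101 and 81, exonic chr5:167516581-167615430 with 48, 62 and 47, exonic chr10:110680099-110690679 with 46, 60 and 40, exonic chr13:106893746-106944389 with 32, 50 and 49, intergenic chr20:25817478-25826661 with 22, 34 and 23, and exonic chr17:15998571-16003404 with 25, 40 and 15. The main tables list only circRNAs whose back-splice share of reads at their ends reaches a minimum, so an unlisted circRNA is not a measured 0, and no fold is given. The second caller listed 7 of these 8 in at least 1 library of the group that lacked them. At chr1:244630341-244664389 it gave 143, 130 and 124 reads in C01 to C03 and 98, 162 and 124 in C04 to C06, and at chr13:106859710-106862333 it gave 97, 72 and 70 against 52, 100 and 69. By the second caller's counts none of the 7 passed the test, and 4 of them had a log2 difference of the opposite sign.

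**Figure D1:**
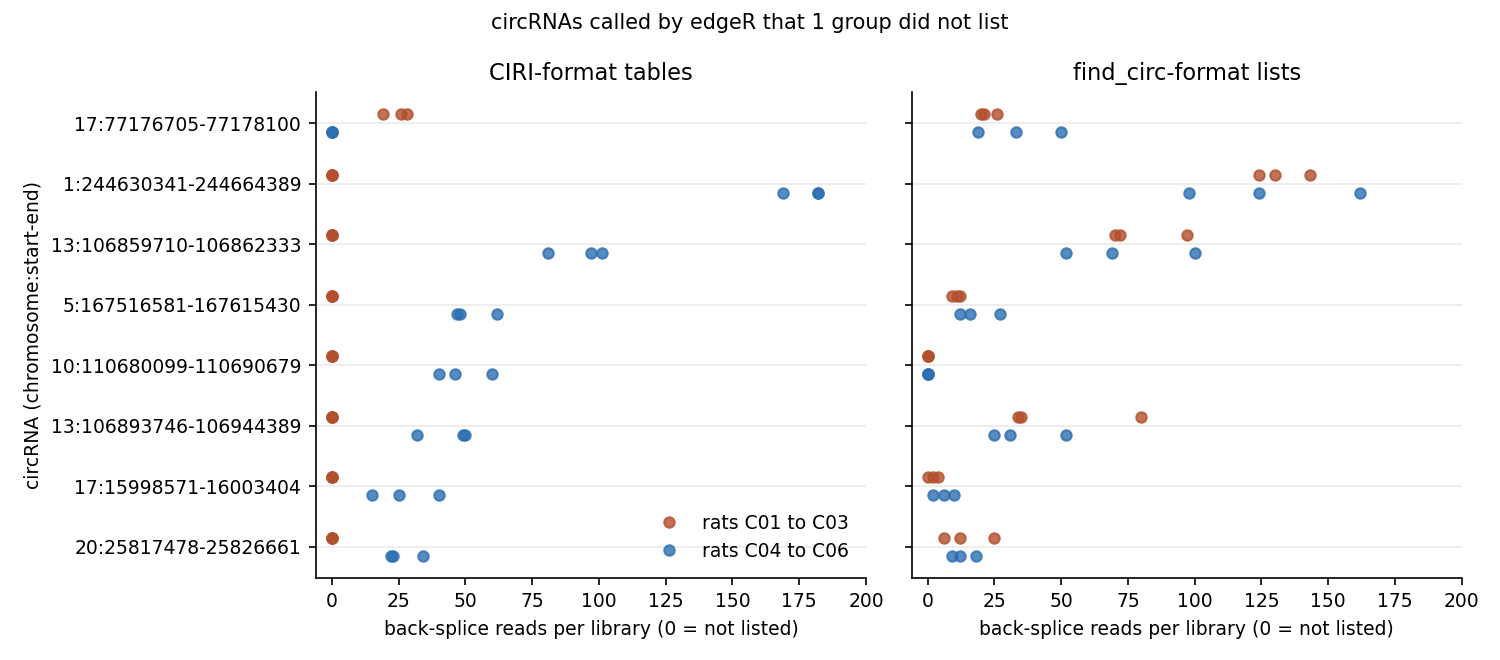
Back-splice reads per library (x axis) of the 8 circRNAs (y axis) that passed the test but were listed in only one group by the main tables, for the main tables (left) and the second caller's lists (right); each point is 1 rat, coloured by group. For chr1:244630341-244664389 the main tables have 182, 182 and 169 reads in C04 to C06 and no listing in C01 to C03, while the second caller has 98 to 162 reads in all 6 libraries.

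Below the threshold, the next circRNAs higher in C01 to C03 by unadjusted p were exonic chr1:52414237-52444705 with 16, 13 and 21 reads (adjusted p 0.078) and intronic chr19:34249087-34272192 with 10, 17 and 8 reads (adjusted p 0.17), both unlisted in C04 to C06 by the main tables. Leaving out 1 rat, from C01 to C06, left 7, 9, 14, 3, 1 and 2 calls. Among the 4 circRNAs listed in every library, chr3:104816866-104818862 was not called without C03, C04, C05 or C06 (adjusted p 0.074 to 0.24), chr4:184195264-184224636 was called only without C03, and the other 2 were not called whichever rat was left out. Their log2 differences without 1 rat stayed at 0.57 to 0.76 and 0.61 to 0.71 for the first 2, -0.56 to -0.45 at chr3:172518176-172524861 and -0.31 to -0.26 at chr2:240854068-240867796. The second caller's own counts gave 2 calls among 2208 circRNAs, while DESeq2 and limma-voom gave 28 and 33 from the main counts.

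Restricting the test to the 273 circRNAs listed in every library, a step added after the data were seen, gave 7 calls, 5 higher and 2 lower in C01 to C03. Chr3:104816866-104818862 (log2 difference 0.71, SE 0.09, adjusted p 3.6e-12) and chr4:184195264-184224636 (0.69, SE 0.12, adjusted p 3.6e-06) led, and both were called in all 10 alternatives of this test, which include DESeq2, limma-voom and leaving out each rat (adjusted p 7.1e-25 to 0.0032 and 1.6e-06 to 0.014). Also higher were intergenic chr2:251176578-251376470 (1.07, SE 0.28), intergenic chr6:144211592-144275272 (0.52, SE 0.14) and intergenic chr20:5347661-5414567 (0.40, SE 0.09). Lower were chr3:172518176-172524861 (-0.46, SE 0.13) and exonic chr3:97727432-97813284 (-0.86, SE 0.26). The adjusted p of these 5 ran from 0.0010 to 0.038, and each was called in only 3 to 6 of the 10 alternatives. The chr20 difference depended on rat C06, which had 299 reads against 686 and 782 in C04 and C05. Without C06 its log2 difference was 0.10. Its groups overlapped, at 52312 ± 9911 CPM over the 273 in C01 to C03 and 39656 ± 15922 in C04 to C06 (SD, n = 3 each). The test over 772 circRNAs gave it a log2 difference of 0.35 (SE 0.31, edgeR unadjusted p 0.30). The restricted test's small SE and p there do not reflect this spread between rats. For the 2 leading circRNAs the same 6 rats gave an edgeR adjusted p of 0.036 each over 772 circRNAs. In the second caller's lists, restricted in the same way to 644 circRNAs, 4 were called. These included chr3:104816866-104818862 (0.70, SE 0.13, adjusted p 3.5e-05) and chr4:184195264-184224636 (0.94, SE 0.24, adjusted p 0.017). Of the other 5, the second caller had no reads in any library for chr20:5347661-5414567, chr2:251176578-251376470 and chr3:172518176-172524861. At chr3:97727432-97813284 its log2 difference was -1.01 (SE 0.29, adjusted p 0.056), and at chr6:144211592-144275272 it was -0.20 (SE 0.53), of the opposite sign. Over all 2208 of the second caller's circRNAs the chr3 circRNA passed (adjusted p 0.031) and the chr4 circRNA did not (adjusted p 0.56). The call at chr2:240854068-240867796 was not kept in the restricted test (log2 difference -0.26, adjusted p 0.12).

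**Figure D2:**
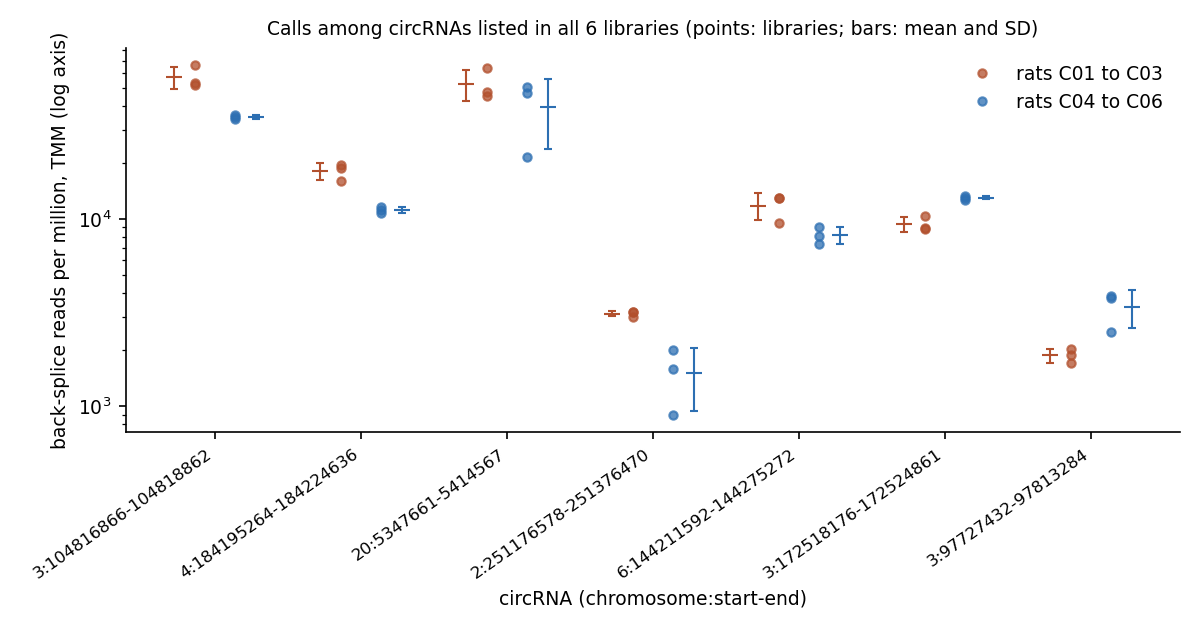
TMM-normalised back-splice CPM (y axis, log scale) of the 7 circRNAs called among those listed in all 6 libraries (x axis); points are libraries, horizontal marks with bars are group means ± SD (n = 3). The 3 libraries of one group lie above the 3 of the other at each circRNA except chr20:5347661-5414567, where the groups overlap.

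Summed per host gene, fewer back-splice reads were listed in C01 to C03 for the gene given as ENSRNOG00000003738, whose 7 circRNAs on chromosome 13 had 33, 27 and 31 reads in C01 to C03 against 207, 234 and 186 in C04 to C06 (edgeR adjusted p 1.2e-05). Most of the C04 to C06 reads came from chr13:106859710-106862333 and chr13:106893746-106944389, which the main tables did not list in C01 to C03, so no fold is given here either. Altogether 5 of 473 host genes passed, 1 higher and 4 lower. The other 4 were genes with no circRNA listed in one group, including ENSRNOG00000011931, host of chr1:244630341-244664389, and ENSRNOG00000017941, host of chr17:77176705-77178100. With the second caller's counts none of 548 host genes passed in edgeR, with 32 at an unadjusted p under 0.05, and ENSRNOG00000003738 had a log2 difference of the opposite sign, 0.19. With the main counts DESeq2 called 20 host genes and limma-voom 26.

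The balance of circular and linear RNA at the same ends differed more sharply at a few loci. At the exonic chr14:87328008-87357732 the circular share of reads was 21.9% ± 1.19 in C01 to C03 against 53.0% ± 2.69 in C04 to C06. At the intergenic chr1:281236389-281256438 it was 11.8% ± 1.36 against 30.6% ± 1.47, and at the exonic chr6:136430192-136436620 it was 23.1% ± 6.65 against 51.0% ± 3.92. It was higher in C01 to C03 at the intronic chr9:82440779-82441203 (48.0% ± 7.37 against 12.1% ± 2.21) and the intergenic chr15:105493588-105495743 (43.5% ± 2.62 against 25.1% ± 1.44; SD, n = 3 each). Of 273 circRNAs, 6 passed in limma on the log2 ratio of circular to linear reads, 2 higher and 4 lower. The adjusted p of these 5 named ran from 0.0021 to 0.033. The chr14, chr1 and chr9 loci were called in all 9 alternatives of this test, including without each rat, the chr6 locus in 4 and the chr15 locus in 2. Exonic chr18:29633808-29634585, at 20% ± 1.07 against 11.4% ± 1.80, did not pass (adjusted p 0.052). The median log2 difference over the 273 was -0.20, with 173 below 0. The median circular share was 25.2% ± 1.73 in C01 to C03 and 28.4% ± 0.741 in C04 to C06 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows).

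Linear reads at the ends of the 273 circRNAs, tested after the data were seen, passed the test at many more loci than the back-splice reads did. At chr9:82440779-82441203 linear reads fell from 463, 463 and 422 in C04 to C06 to 39, 25 and 42 in C01 to C03 (log2 difference -3.66, SE 0.14). At chr14:87328008-87357732 they rose from 144, 189 and 182 to 1002, 679 and 822 (2.27, SE 0.09). Further rises were at chr1:54418421-54455843 (2.01, SE 0.28), exonic chr8:49754717-49757732 (1.76, SE 0.36), intronic chr12:40388299-40397763 (1.47, SE 0.57) and chr1:281236389-281256438 (1.18, SE 0.12). Further falls were at chr15:105493588-105495743 (-1.52, SE 0.08), exonic chr5:79280979-79291689 (-1.27, SE 0.08), chr18:29633808-29634585 (-1.18, SE 0.04) and intergenic chr9:7957095-8015956 (-1.07, SE 0.15). All 10 passed in edgeR; the largest adjusted p was 0.034, at chr12:40388299-40397763, which rested on 3 to 13 reads per library and did not pass without rat C01, C02, C04 or C06 (adjusted p 0.088, 0.16, 0.072 and 0.10). Back-splice reads at these 10 loci had log2 differences between -0.75 and 0.62, none past the threshold.

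In all, 87 of the 273 loci passed for linear reads, 51 higher and 36 lower in C01 to C03, against 7 for back-splice reads. Both kinds of read passed at 3 loci. At chr3:104816866-104818862 linear reads were higher by a log2 difference of 0.86 (SE 0.05) and at chr4:184195264-184224636 by 0.56 (SE 0.13), and at chr3:172518176-172524861 they were lower (-0.49, SE 0.13); the circular share at these 3 loci did not pass (adjusted p 0.36, 0.90 and 0.74). Of 225 loci with 1 circRNA kept per locus, 65 passed for linear reads, and in 46 of these the back-splice difference had the same sign. Across these 225 loci, which are not independent replicates, both differences had a Pearson's r of 0.26 and a Spearman's rho of 0.25 (permutation p of r 0.00020 from 10000 permutations). Both differences come from the same 6 libraries. Each locus also had to keep a circular share of at least 9.09% in every library, which favours differences of the same sign. The permutations do not account for this minimum, so their p is not a test of coupling alone.

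**Figure D3:**
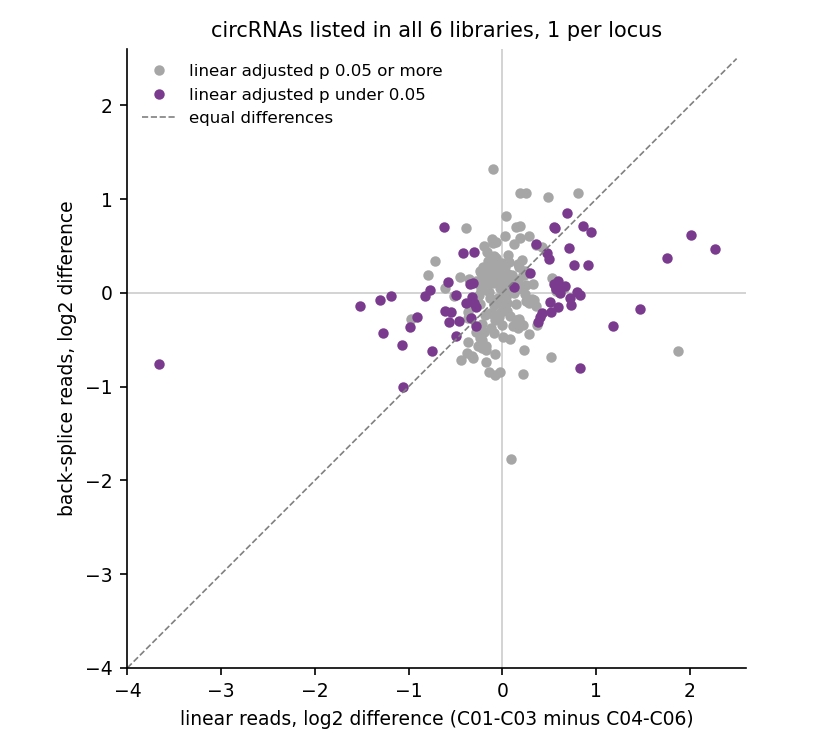
Log2 difference (C01 to C03 minus C04 to C06) of linear reads (x axis) and back-splice reads (y axis) at the same ends, 1 point for each of 225 loci; purple points passed an adjusted p of 0.05 for linear reads and the dashed line marks equal differences. Purple points reach -3.66 on the x axis at chr9:82440779-82441203, where the back-splice difference is -0.75.

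Fewer distinct circRNAs were listed in the C01 to C03 glands, 831 ± 39.9 per library against 960 ± 22.5 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). After thinning every library to 15506 back-splice reads the numbers were 808 ± 12.4 and 900 ± 10.8 (exact permutation p = 0.1). The second caller's lists did not show this, with 4119 ± 105 and 3709 ± 1000 candidates (exact permutation p = 0.6). Intergenic circRNAs made up 30.6% ± 0.489 of the circRNAs in C01 to C03 and 28.9% ± 0.211 in C04 to C06, and exonic ones 61.3% ± 0.210 and 62.5% ± 0.745 (exact permutation p = 0.1 each). Intronic shares were 8.12% ± 0.617 and 8.54% ± 0.560 (exact permutation p = 0.5).

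Group-specific listing leaned toward C04 to C06 in the main tables, and the second caller's lists did not show this. The main tables listed 13 circRNAs in all of C01 to C03 and none of C04 to C06, and 35 the other way round, 48 in total, where the other 9 splits of the libraries gave 13 to 24. These counts were not matched for depth. The main tables had 17971 ± 2815 back-splice reads per library in C01 to C03 and 20815 ± 1387 in C04 to C06 (SD, n = 3 each). In the second caller's lists, an alternative added after the data were seen, 36 circRNAs were listed only in C01 to C03 and 27 only in C04 to C06. The total of 63 was below the 65 to 81 of the other splits. C04 had the shortest of these lists, with 2843 candidates, which limits how many circRNAs all of C04 to C06 can share. Within a library, 63.4% ± 4.79 (SD, n = 6) of the circRNAs in the main tables had the same ends in the second caller's list, and these made up 14.7% ± 2.25 of that longer list. For circRNAs found by both, log2 read numbers correlated across circRNAs with a Pearson's r of 0.860 to 0.872 per library.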

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

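The test of the second caller's circRNAs listed in all 6 libraries was added after the data were seen. The following candidates of the second caller lie outside the main tables, so the comparisons above that rest on those tables do not use them. The second caller listed 12896 circRNAs that the main tables lacked, 266 of them in all 6 libraries. The reads of 4 of these are given here, 2 because they were called among the second caller's circRNAs listed in all 6 libraries and 2 more because they had among the most reads. At chr5:90818736-90827570 it counted 2008 reads over the 6 libraries, with 33680 ± 5178 CPM in C01 to C03 and 18478 ± 2294 in C04 to C06 (SD, n = 3 each; log2 difference 0.86, SE 0.15, edgeR adjusted p 4e-06). The main tables list another circRNA with the same end, chr5:90817794-90827570, in all 6 libraries. It did not pass the restricted test there (log2 difference -0.09, SE 0.24, edgeR adjusted p 0.93). At chr6:133825329-133826293 the second caller counted 154 reads, with a log2 difference of -1.44 (SE 0.35, edgeR adjusted p 0.0089). At chr3:67723614-67757148 and chr5:58994723-58994911 it counted 1572 and 1496 reads, and neither passed (adjusted p 0.85 and 0.22).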

How the results depend on the processing

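The alternatives for the tests restricted to circRNAs listed in all 6 libraries and for linear reads were chosen after the data were seen, as were the averaged reads and the second caller's sharing count. The 12 circRNA calls became 41 without a filter, 28 with DESeq2, 33 with limma-voom, 31 with the authors' TPM at either pseudocount, 2 with the second caller's counts, 6 with the authors' averaged reads, 7 among circRNAs listed in all 6 libraries and 4 among those of the second caller; leaving out 1 rat gave 1 to 14. RLE, library size only, both stricter filters and circRNAs found by both callers gave 9 to 12. The 5 host gene calls became 23 without a filter, 20 with DESeq2, 26 with limma-voom, 0 with the second caller's counts (32 at an unadjusted p under 0.05), 2 with circRNAs found by both callers and 0 with circRNAs listed in all 6 libraries (18 at an unadjusted p under 0.05), and 2 to 4 without 1 rat (2 without C05 or C06, 3 without C02 or C04). The 6 circular share calls became 12 with a pseudocount of 2, 3 with circRNAs listed in at least 4 libraries, and 3 to 5 without 1 rat (3 without C03, C04 or C05). The 7 calls among circRNAs listed in all 6 libraries became 11 with library size only (5 higher, 6 lower, against 5 and 2), 2 with DESeq2, and 2 to 8 without 1 rat (2 without C04, 4 without C01, C05 or C06). The 87 linear read calls stayed within 63 to 99 in all 11 alternatives run.

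Among circRNAs and host genes named from the tests chosen beforehand, direction turned with the second caller's counts and with no other alternative run. The log2 difference became -0.64 at chr17:77176705-77178100 (-0.65 when restricted to all 6 libraries), 0.050 at chr13:106859710-106862333 (0.0462), 0.40 at chr13:106893746-106944389 (0.40) and 0.0302 at chr20:25817478-25826661 (0.0221). Among host genes it became -0.64, -0.0551 and 0.19. The dropping of entries from the main tables is one difference between the callers; the cause was not tested. Of 254 other values of the 14 named circRNAs, 167 stayed on their side of the threshold, 70 lost it and 9 gained it. For the 10 loci named for linear reads, 105 of 110 stayed. The number of circRNAs per library in C01 to C03 was 86.6% of that in C04 to C06 and 111% with the second caller, and 84.4% to 88.5% without 1 rat. The difference in exonic share (-1.23 percentage points) was -3.51 by reads and -2.35 at 5 or more reads, and the intergenic one (1.65) was 3.55 and 2.22. The intronic difference (-0.417) was 0.130 at 5 or more reads (exact permutation p 0.5 and 0.9). The 48 circRNAs listed by one group became 27 at 5 or more reads. For each of these the cause was not tested. Gene list tests, and their 3 alternatives, were not run because IDs could not be paired with symbols. At 15506 to 22265 back-splice reads per library, the circRNA test recovered 14 of 100 simulated 4-fold changes over 770 circRNAs. Over the 273 listed in all 6 libraries it recovered 45 of 45, with the same 3 rats per group (biological coefficient of variation 80.7% and 11.9%). The 80.7% includes unlisted entries counted as 0. The simulation did not apply the minimum circular share, under which a real change can take a circRNA out of the 273.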

Other observations

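The tests of the minimum circular share, of absence by the second caller, of chr3:104816866-104818862 and of the correlation below were chosen after their results had been seen, and the restricted and linear read tests were added after the data were seen.

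Listing by one group only. With 5 or more reads in every library of one group and no listing in the other, 27 circRNAs stood out in the main tables, 20 of them listed in C04 to C06, against at most 10 in any other split. These counts were not matched for depth. Absence of the circRNA from every library of the group that lacked it is argued against for most of the 27. The second caller had reads in at least 1 library of that group for 22 of 27 (81.5%). Some of these rest on 1 library, such as chr6:109729890-109745287 with 0, 0 and 2 reads in C01 to C03. Over those the second caller lists anywhere, its reads too leaned toward the listing group (median log2 difference 0.58). Where listed, their median circular share was 12%, just below 12.4%, the 25th percentile of all listings with 5 or more reads, so that 1.36 times as much linear RNA (median) would take them under the table's minimum of 9.09%. At the 4 host genes with another circRNA listed in all 6 libraries, linear reads were higher in the group that did not list the circRNA in all 4 (median log2 difference 0.32), but these hosts had circRNAs needing only 1.03 to 1.31 times the linear RNA, against 1.87 at chr1:244630341-244664389, 2.92 at chr13:106859710-106862333 and at most 3.94. A candidate explanation for those nearest the minimum is therefore higher linear RNA, with or without fewer circles. For the others it was not tested and stays open, as does a day and night difference. One of these, chr7:32955133-32982696, has no host gene but shares its end with chr7:32922004-32982696, which was listed in all 6 libraries. Linear reads at that shared end were not used here.

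More calls from linear than from back-splice reads. Over the 273 circRNAs listed in every library, linear reads gave 87 calls and back-splice reads 7. Greater depth is argued against as the whole cause: with linear reads thinned to each library's back-splice total, 20 draws gave a median of 46.5 calls and at least 38. Counting the same linear reads for several circRNAs of one locus is argued against as well, since a fit with 1 circRNA per locus had 28.0% called from linear reads and 4.00% from back-splice reads. Larger changes of linear RNA and smaller variation of its counts between rats (biological coefficient of variation 8.03% against 11.9%) both stay open, as does a day and night difference. The median absolute log2 difference was 0.23 for linear and 0.26 for back-splice reads. This does not settle it, since noise adds to both and more so at the lower back-splice counts.

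Higher back-splice reads at chr3:104816866-104818862 in C01 to C03. A caller difference is argued against, since the second caller's log2 difference was 0.70 (SE 0.13) beside 0.71 in the main tables. A larger circular share is argued against too, since the circular to linear ratio had a log2 difference of -0.33 (SE 0.20). Linear reads at the same ends were higher as well (log2 difference 0.86, SE 0.05); what raised both was not tested, and whether C01 to C03 are the day or the night group stays open because of the labels.

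Whether back-splice reads in general follow the linear reads of the same ends cannot be told apart from weak coupling here. Pearson's r was 0.26 over 225 loci, between the bounds set for either reading. The part of low read numbers, and of the minimum circular share that every locus had to meet, was not tested.

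For each test across many circRNAs or genes, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. In each case 1 split, the real one, gave as many calls as observed: 12 circRNA calls against at most 1 in the other splits, 5 host genes against 1, 6 circular shares against 1, 87 linear read calls against 0, and 7 calls among circRNAs listed in all 6 libraries against 0.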
